A study of Mus musculus with 8 samples.

How the data were processed

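The data are 8 RNA-seq libraries from embryonic mouse kidney, each made from total RNA with 2 μg of input per the labels' protocols. Reads were trimmed with Trimmomatic and aligned with STAR against mm10, as far as the names given in the submitters' processing notes tell, without versions. How reads were assigned to transcripts is not given in the sources used here. The deposited values are TPM per RefSeq transcript, made by the authors, with 1 table per library and 32862 transcripts (28523 NM and 4339 NR) in each. Each library sums to 1000000.

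Transcripts were summed per gene symbol into 24151 genes. In the files 52 symbols were listed as dates or numbers, and these were restored from their RefSeq identifiers with the RefSeq gene table of GRCm38.p6; 134 symbols that are themselves accessions were kept as listed. Transcript lengths were taken from GENCODE M21 sequences through their RefSeq links. Gene coordinates are from the RefSeq table, and GRCm38 is the assembly that mm10 names. A gene with several RefSeq transcripts was mostly near 0: 22.7% of the 4777 such genes had a mean of at least 1 TPM, against 60.9% of the 19374 genes with 1 transcript. The low values of such genes were not read as low expression. TPM keeps no depth. The step of which the largest share of low values were whole multiples, within a tolerance of 0.02, was taken as 1 read. That share was not recorded. By this estimate 1 read in 1 kb of transcript was worth 0.0609 to 0.105 TPM, which limits what can be seen of rare transcripts.

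The test was planned for counts, and because the files hold TPM the planned form for normalized values was used: limma with a mean-variance trend and robust variance moderation on log2(TPM + 1), with a filter of at least 1 TPM in at least 2 libraries (13677 genes). A fold change on this scale understates the change of low genes. Stage and agent were terms of 1 fit (3 residual degrees of freedom), which gave the comparison of CPF with DMSO and of E18.5 with E12.5. An agent by embryonic day term (4 residual degrees of freedom) asked for different slopes. Adjusted p are Benjamini-Hochberg over all tested genes, with calls under 0.05. Each stage has 1 library per agent, so differences within a stage carry no p. Nothing says how many animals a library holds. With stage in the fit, the spread behind the p-values is how the CPF minus DMSO difference varies between stages. For slopes it is the departure of libraries from a straight line over embryonic day in each agent. Neither measures the spread between animals.

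Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the 40 lists with at least 4 measured members. The mitochondrially encoded list had 0 measured members, and X inactivation had 1, Xist (-0.02 ± 0.39 in CPF minus DMSO), so neither was tested. At each stage a list's median log2 ratio was set against 10000 random lists of the same size matched on mean expression. The placement of CPF libraries used genes with a mean of at least 5 TPM and an absolute log2 difference of at least 2 between DMSO E18.5 and E12.5, a piecewise linear DMSO course, least squares, and 1000 resamplings of the genes.

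The genes named were fixed by rule. Across stages these were called genes of the same sign at 4 stages, up to 10 each way by p. Between E18.5 and E12.5 they were the 10 largest log2 fold changes each way among called genes with a mean of at least 20 TPM. For the slopes they were 5 each way by p, and for each stage the 6 highest and 6 lowest ratios among genes with a mean of at least 10 TPM. A set of 19 kidney, organophosphate and stress genes was always named, and up to 4 called members of each list described, or else the 2 with the highest mean. Unnamed gene models were left out, and some genes that the rule names are not reported here. Ret and Cited1, which have several RefSeq transcripts, are given as library values only, a choice made after their values were seen. Fold changes are given for Spred1 and Xist, which have 2 RefSeq transcripts each. Further genes of pancreas, gonad, liver and lung were listed after the first results and before their own values were examined.

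The procedures were tested on simulated data with 200 changed genes among 13677. Across stages, 19.4, 67.2 and 95.5% of genes changed by 1, 2 and 3 log2 units were called, with 3 false calls. Between E18.5 and E12.5, 2.99, 31.3 and 87.9% of genes changed by 1, 2 and 4 log2 units were called, with 1 false call. For slopes, 32.0 and 82.0% of genes changed by 0.5 and 1 log2 units per day were called, with 3 false calls. The placement of 4 simulated libraries, made from the DMSO course with independent noise, was off by at most 0.2 days. Genes were simulated independently, so differences shared by many genes, or departures of CPF libraries from the course, did not enter.

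The alternatives tried were quantile normalization, no filter, a filter of 5 TPM in 4 libraries, a pseudocount of 0.1, leaving out each stage pair, stage left out, embryonic day as a linear covariate and other limits for the placement, and, chosen after seeing the data, scaling to coding transcripts, genes with 1 RefSeq transcript and leaving out E14.5 with E16.5. Planned count-based alternatives were not run because the values are not counts. The tools were Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.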

Results

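Kidneys of mouse embryos of the outbred ICR stock were profiled by RNA sequencing after their mothers had received chlorpyrifos (CPF), an organophosphate insecticide whose oxon inhibits acetylcholinesterase, or the solvent DMSO alone. The dose was 5 mg per kg under the skin each day from gestation day 7.5 to 11.5, and kidneys were taken at 4 stages, 2 days apart, from E12.5 to E18.5. The 8 libraries comprise 4 CPF and 4 DMSO libraries, 1 of each per stage, and how many embryos or litters entered a library is not given in the sources used here. The values are TPM and sum to 1000000 in each library, so depth is not read from them directly. The steps estimated from the low values imply a depth, in units of 1000000 reads, of 19.6 to 27.8 per library. Between 11714 and 12870 genes reached 1 TPM. Genes for which RefSeq lists several transcripts were near 0 in these values (median 0.142 TPM for 4777 genes, against 3.64 TPM for 19374 genes with 1 transcript), and Gapdh, which every cell uses, was at or below 0.926 TPM in all 8 libraries. A low value of such a gene is therefore only a listed value. The RNA components of RNase P and RNase MRP, Rpph1 and Rmrp, together took 19.3, 20.7, 21.8 and 21.3% of the TPM in the CPF libraries from E12.5 to E18.5, and 19.6, 23.6, 31.0 and 41.8% in the DMSO libraries. In a principal component analysis of 2000 genes the first component (51.7% of the variance) ran with stage, and the second (24.8%) placed the CPF libraries of E14.5 and E16.5 at -41.9 and -44.1, apart from the 6 other libraries at 1.10 or above.

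**Figure D1:**
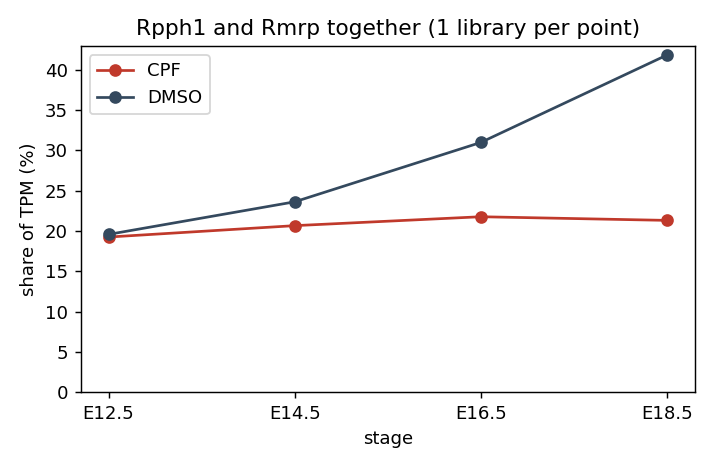
Share of each library's TPM taken by Rpph1 and Rmrp together (vertical axis, percent) by stage (horizontal axis), with 1 library per point, CPF in red and DMSO in dark blue. The DMSO libraries run from 19.6% at E12.5 to 41.8% at E18.5, and the CPF libraries stay between 19.3 and 21.8%.

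Across the 4 stages, 21 genes were higher and 1 was lower in CPF than in DMSO libraries. The metallothioneins Mt1 and Mt2, which bind zinc and copper and are induced by metals and glucocorticoids, were higher by 2.18 ± 0.23 and 1.79 ± 0.27 on the log2 scale (SE, n = 4 stage pairs). Carbonic anhydrase 2 (Car2) was higher by 2.21 ± 0.23, and Junb, an immediate early transcription factor of the AP-1 family, by 2.10 ± 0.29. The smooth muscle actin Acta2 and the cardiac actin Actc1 were higher by 1.50 ± 0.22 and 1.72 ± 0.25, and Akr1b7, an aldose reductase of adrenal cortex and renin cells, by 2.01 ± 0.29. Serpinf2 and Serpina10, serpins that liver secretes, and Ambp, the precursor of alpha-1-microglobulin, were higher by 2.21 ± 0.25, 2.12 ± 0.31 and 3.18 ± 0.40. The 1 lower gene was the microRNA precursor Mir6407, at -2.07 ± 0.33, with values between 0 and 8.75 TPM. Its transcript is far shorter than 1 kb, where 1 read was worth 0.0609 to 0.105 TPM, so its values rest on few reads. All 22 had the same sign at all 4 stages. The list of liver genes, 3.44 above all genes on the log2 scale, was also higher in CPF at all 4 stages. How far RNA of liver, blood, muscle or other organs raised the 21 higher genes was not tested.

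The adjusted p from limma was 0.00391 for Car2, Mt1 and Serpinf2, 0.0222 for Junb, Ambp, Akr1b7, Acta2, Actc1 and Serpina10, 0.0243 for Mt2 and 0.0328 for Mir6407, over 13677 genes tested. In TPM, Car2 read 89.7, 435, 237 and 217 in CPF kidneys from E12.5 to E18.5 against 19.4, 57.7, 51.7 and 70.8 in DMSO kidneys. Mt1 read 20.4, 127, 191 and 145 against 5.67, 31.2, 33.6 and 23.7. On GRCm38, Car2 lies on chromosome 3 at 14886269 to 14900770, and Mt1 and Mt2 lie side by side on chromosome 8 at 94178883 to 94180327 and 94172618 to 94173567. Junb lies on chromosome 8 at 84976909 to 84978748, Acta2 on chromosome 19 at 34240336 to 34255585, Actc1 on chromosome 2 at 114047282 to 114052875 and Akr1b7 on chromosome 6 at 34412362 to 34423137. Serpinf2 is on chromosome 11 at 75431736 to 75439501, Serpina10 on chromosome 12 at 103616675 to 103631490, Ambp on chromosome 4 at 63143275 to 63154172 and Mir6407 on chromosome 19 at 53010656 to 53010756. The calls depended on the scaling. With quantile normalization 0 genes passed in limma (1485 at an unadjusted p under 0.05), and with libraries scaled to their coding transcripts 1 passed (Mt1), although all 22 kept their sign in both and had an unadjusted p under 0.05 with quantile normalization. The fold changes moved little: with quantile normalization and with coding scaling Car2 differed by 2.02 and 2.04, Mt1 by 1.96 and 2.02 and Ambp by 2.96 and 3.19. The count was also 0 in limma without the filter on low values, with stage left out and with embryonic day as a linear covariate (1537, 656 and 1262 genes at an unadjusted p under 0.05), 92 with a stricter filter, 98 without the E12.5 pair, 221 without E14.5, 25 without E16.5, 51 without E18.5 and 34 without both E14.5 and E16.5. Of the 22 genes these hold 17, 21, 22, 7, 13 and 2.

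Genes of the nephron progenitor, the cap mesenchyme cell that forms nephrons, lay lower in the CPF kidneys. Of 16 listed genes 13 were below 0, with a list median of -0.67 on the log2 scale, or -0.82 relative to all genes, whose median was 0.15. Six2, the transcription factor that maintains the progenitor, differed by -1.32 ± 0.25 and was lower at 4 of 4 stages (adjusted p = 0.0648 with limma over all genes). It read 82.3, 50.5, 41.6 and 35.1 TPM in DMSO from E12.5 to E18.5 and 45.6, 18.1, 19.1 and 8.38 TPM in CPF. Gdnf, the ligand that progenitors send to the ureteric bud, differed by -0.88 ± 0.24 (adjusted p = 0.171 with limma), also lower at 4 of 4 stages. None of the 16 passed over all genes tested, and 8 were lower adjusted over the list alone. The list passed limma's camera (adjusted p = 3.13e-15), with an adjusted p = 0.123 with an estimated correlation. That correlation was -0.058, below the preset 0.01, so the larger p does not come from correlation among the members. With the preset correlation camera's p rests on the spread over genes, not over the 4 stage pairs. The progenitor list was also the only list of the 40 that passed fry, a test of a shared direction among its genes (adjusted p = 0.0105). Crym (-0.74 ± 0.26) and Itga8 (0.12 ± 0.20) had the highest means of the list. Cited1, a gene with 4 RefSeq transcripts, read 0.539, 1.13, 1.04 and 0.669 TPM in CPF and 0.722, 2.14, 1.48 and 3.96 TPM in DMSO.

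The Hox genes, which set position along the body axis, were also lower as a group: 31 of 35 were below 0, with a median of -0.60 relative to all genes (camera adjusted p = 9.40e-21, and adjusted p = 0.451 with an estimated correlation), and 1 was lower adjusted over the list alone. From E12.5 to E18.5 the Hox list lay at -0.56, -0.57, -0.87 and -0.53 relative to all genes. At E18.5 its own median log2 ratio was 0.0030, with 18 of 35 genes higher in CPF. Dilution by RNA of other organs was not tested for this list. Hoxd10 and Hoxd4, the members with the highest means, differed by -0.42 ± 0.28 and -0.75 ± 0.25. Foxd1, which marks the progenitors of the renal stroma, differed by -1.08 ± 0.22 (adjusted p = 0.0914 with limma) and was lower at 4 of 4 stages. The renal stroma list as a whole lay at -0.14 relative to all genes (camera adjusted p = 0.0949). The list of genes that respond to GDNF-RET and FGF signals lay at -0.19 (camera adjusted p = 0.00778, and adjusted p = 0.451 with an estimated correlation), with Dusp6 at 0.14 ± 0.21 and Spred1 at 0.29 ± 0.20. Replication-dependent histone genes lay at -0.30 relative to all genes (camera adjusted p = 5.63e-06, and adjusted p = 0.581 with an estimated correlation), with a mean of -0.0092 on the log2 scale.

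**Figure D2:**
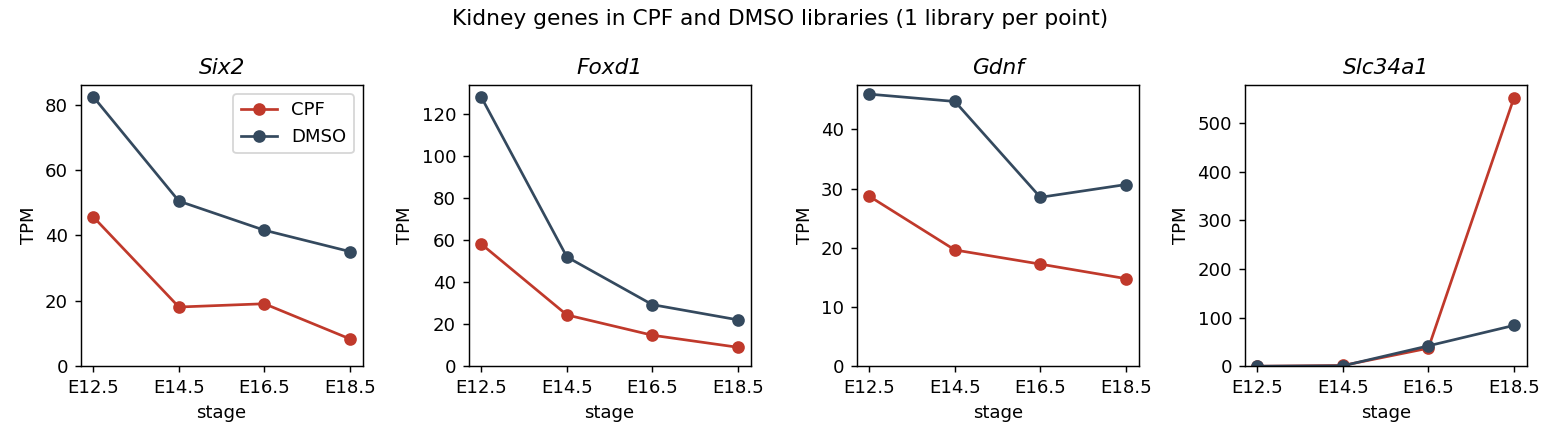
TPM (vertical axes, from 0) of 4 kidney genes by stage (horizontal axes), with 1 library per point, CPF in red and DMSO in dark blue. Six2, Foxd1 and Gdnf are lower in CPF at each stage, and Slc34a1 reads 551 TPM in CPF against 83.9 TPM in DMSO at E18.5.

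Of the lists of differentiated nephron segments, the proximal tubule list passed camera across stages. In it 21 of 21 genes were above 0, with a median of 0.64 relative to all genes (camera adjusted p = 3.83e-06, and adjusted p = 0.562 with an estimated correlation). Relative to all genes the list lay at 0.44, 0.27, -0.24 and 1.96 from E12.5 to E18.5. The liver list lay at 2.27, 2.12, 5.80 and 2.82 at these stages. How far liver RNA raised the proximal tubule list was not tested. Lrp2 (megalin) differed by 0.48 ± 0.51 and Spp2 by 1.42 ± 0.36. The collecting duct, podocyte, loop of Henle and distal tubule, and early nephron lists lay at 0.30, 0.26, 0.18 and 0.10 relative to all genes, with camera adjusted p of 0.0928, 0.809, 0.243 and 0.176. The ureteric bud list lay at -0.13 (camera adjusted p = 0.151), and the gene at its median was Ret, which has 2 RefSeq transcripts. Without the E18.5 pair the early nephron, podocyte, and loop and distal tubule lists turned to -0.023, -0.14 and -0.15. The endothelium list had a median of 0.11 relative to all genes but a negative direction in camera (adjusted p = 0.931). The list of mural and renin cells lay at 0.44 (camera adjusted p = 0.000896, and adjusted p = 0.451 with an estimated correlation), with Acta2 and Akr1b7 called over all genes. Akr1b7, also a gene of adrenal cortex, read 18.0, 306, 229 and 54.5 TPM in CPF and 5.26, 35.0, 55.0 and 21.4 TPM in DMSO. The adrenal cortex list lay at 1.22, 3.02, 5.25 and -0.26 relative to all genes at these stages. Ren1 was at or below 0.148 TPM in each library. How far adrenal RNA raised the list was not tested.

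In the test across stages, transcripts of organs that lie beside the kidney, and of blood and muscle, were higher in the CPF libraries, although at E18.5 only the liver list was far above all genes. Of the liver genes, 13 of 13 were above 0 and passed adjusted over the list alone, with a median of 3.44 relative to all genes (camera adjusted p = 2.58e-25), and Ambp passed over all genes. The adrenal cortex list, steroid-making enzymes such as Hsd3b1 (3.93 ± 1.09) and Cyp11a1 (3.23 ± 0.84), lay at 2.02 (9 of 9 above 0, adjusted p = 1.44e-08). The erythroid list lay at 1.61 (10 of 10, adjusted p = 3.73e-07), with Hbb-y at 0.69 ± 0.73 and Hba-x at 0.45 ± 1.06. The skeletal muscle list lay at 0.99 (8 of 9, adjusted p = 0.000335), with Mylpf at 1.17 ± 0.28 and Myh3 at 1.16 ± 0.29. The sympathoadrenal list lay at 1.10 (11 of 11, adjusted p = 1.26e-05), with Chgb at 1.37 ± 0.68 and Dbh at 1.52 ± 0.72. The gonad and germ cell list lay at 0.91 (7 of 7, adjusted p = 0.000417), with Sycp3 at 1.00 ± 0.39 and Dppa3 at 2.10 ± 1.37. Macrophage genes lay at 0.50 (12 of 12, adjusted p = 1.70e-06), with Lyz2 at 1.09 ± 0.26 and Tyrobp at 0.59 ± 0.26. At E18.5 the adrenal cortex, sympathoadrenal, gonad, skeletal muscle and erythroid lists lay at -0.26, -0.53, -0.27, -0.13 and -0.73 relative to all genes, macrophage genes at 0.16 and liver genes at 2.82. With an estimated correlation the adjusted p was 0.469 for the sympathoadrenal list and 0.451 for the 6 others. Cartilage lay at 0.020, with a negative direction in camera (adjusted p = 0.815).

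**Figure D3:**
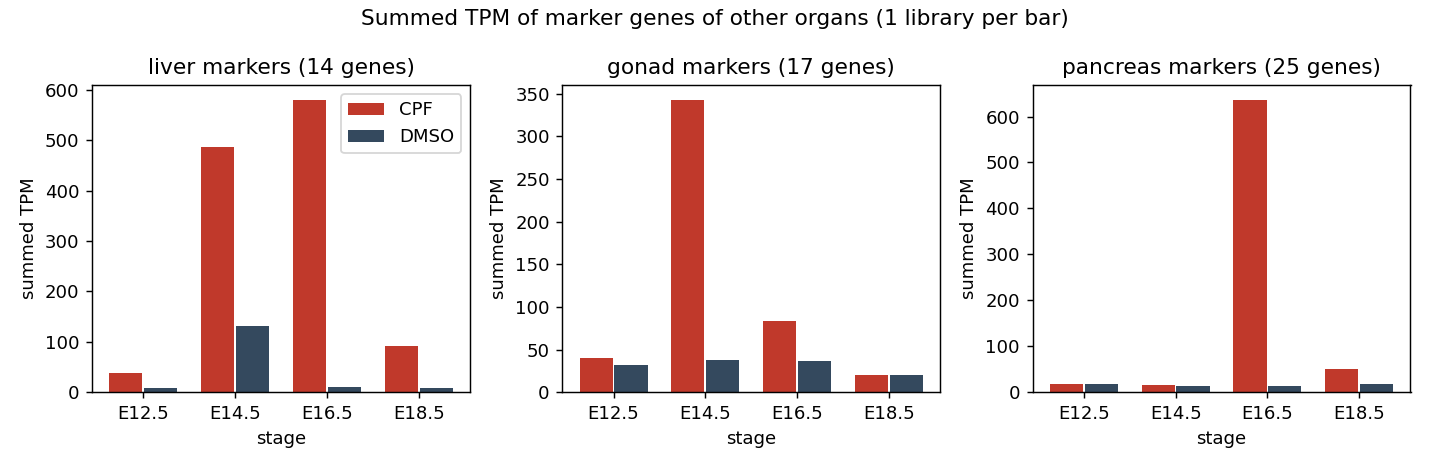
Summed TPM (vertical axes, from 0) of further marker genes of liver, gonad and pancreas by stage (horizontal axes), with 1 library per bar, CPF in red and DMSO in dark blue. The pancreas genes sum to 637 TPM in CPF and 14.6 TPM in DMSO at E16.5, and the gonad genes to 343 and 38.1 TPM at E14.5.

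Immediate early genes lay at 0.87 relative to all genes (14 of 14 above 0, 11 adjusted over the list alone, camera adjusted p = 1.63e-12, and adjusted p = 0.451 with an estimated correlation), with Junb called over all genes. Several response lists lay higher by less. The medians relative to all genes were 0.31 for oxidative stress genes (camera adjusted p = 0.000773), 0.42 for organophosphate targets and cholinergic genes (0.00175), 0.30 for xenobiotic metabolism (0.00175), 0.53 for interferon response (0.00089), 0.61 for renal endocrine genes (0.00175), 0.30 for collagen and matrix (0.000417), 0.28 for hypoxia (0.00294) and 0.26 for cholesterol biosynthesis (0.00778). Not all of these lists were higher at every stage. From E12.5 to E18.5 the renal endocrine list lay at 0.16, 0.31, -0.30 and 1.27, cholesterol biosynthesis at -0.28, 0.16, 0.62 and 0.54, and collagen and matrix at 0.31, -0.017, 0.55 and 0.42. With an estimated correlation, the adjusted p was 0.469 for collagen and matrix, 0.571 for hypoxia, 0.667 for cholesterol biosynthesis and 0.451 for the other 5. How far RNA of liver (3.44 relative to all genes) and of other organs raised these lists was not tested. Bche and Pon1 of the organophosphate list, for example, are also made by liver. Named members were Prdx1 (0.28 ± 0.25) and Sod1 (0.25 ± 0.20) for oxidative stress, Lypla1 (0.33 ± 0.24) and Apeh (0.16 ± 0.23) for organophosphate targets, Fmo1 (1.49 ± 0.33) for xenobiotic metabolism, Agtr2 (0.80 ± 0.25) for the endocrine list and Ndrg1 (1.19 ± 0.41) for hypoxia, and none of these passed over all genes. Lists that did not pass camera were inflammation (0.32 relative to all genes, adjusted p = 0.0949), autophagy (0.17, 0.0702), nuclear oxidative phosphorylation (0.082, 0.127), Notch pathway (0.095, 0.507), ER stress (0.038, 0.497), Wnt targets (-0.014, 0.903), p53 targets (-0.030, 0.975), cytoplasmic ribosomal proteins (-0.090, 0.0694), cell cycle (-0.13, 0.324) and Y-linked genes (0.32, 0.0686).

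Bche, the serum cholinesterase and a direct target of organophosphates, differed by 0.69 ± 0.27 (adjusted p = 0.414 with limma). Pon1, the paraoxonase that hydrolyses chlorpyrifos oxon, differed by 0.84 ± 0.30 (adjusted p = 0.360 with limma). Both are also made by liver, and both were higher in CPF at 4 of 4 stages, as the liver list was (3.44 relative to all genes). Ache, with 2 RefSeq transcripts, was listed at 0 in all 8 libraries. Hmox1 differed by 0.79 ± 0.25 (adjusted p = 0.266) and the proliferation gene Mki67 by 0.41 ± 0.20 (adjusted p = 0.560). Wnt4, Nphs1, Slc34a1 and Aqp2 differed by 0.30 ± 0.36, 0.57 ± 0.45, 0.76 ± 0.45 and 0.45 ± 0.36, with adjusted p of 0.874, 0.791, 0.674 and 0.786. Ret read 0.799 to 1.98 TPM over the 8 libraries, and Wnt11, Umod, Ren1 and Cyp1a1 were at or below 0.359, 0.0398, 0.148 and 0.0359 TPM in each.

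At each stage the comparison sets 1 CPF library against 1 DMSO library, so it has no replicate check. Genes with a mean of at least 5 TPM that differed by more than 2-fold numbered 339 higher and 169 lower in CPF at E12.5, 409 and 113 at E14.5, 526 and 169 at E16.5, and 2242 and 103 at E18.5. Nephron progenitor and Hox genes were at or below percentile 0.03 of 10000 matched random lists at every stage, and liver genes at percentile 100 at every stage. At E18.5 the median log2 ratio of all genes was 0.53, against 0.14 with libraries scaled to coding transcripts. That scaling gave 982 higher and 275 lower genes at E18.5 (78.1% higher, against 95.6% before) and 411 and 285 at E16.5 (59.1% higher, against 75.7%).

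**Figure D4:**
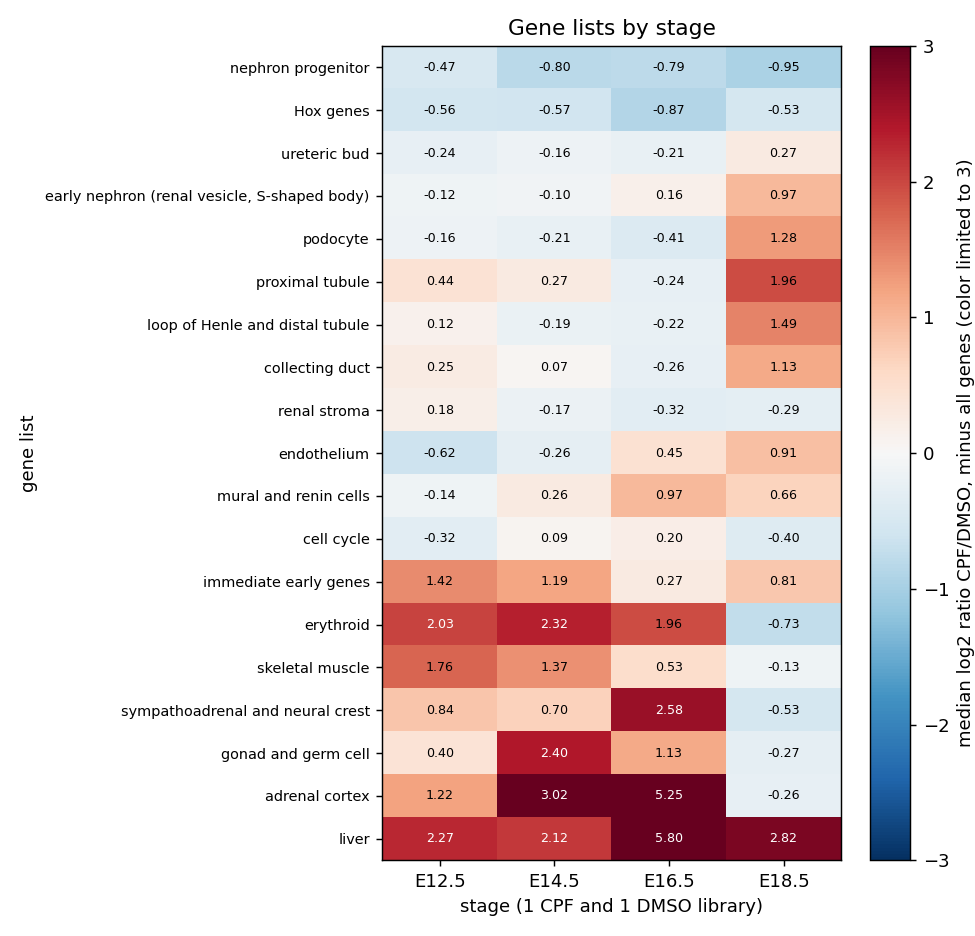
Median log2 ratio of CPF to DMSO in 19 gene lists (rows) at 4 stages (columns), minus the median of all genes, with red above and blue below 0. The nephron progenitor list runs from -0.47 to -0.95 and the liver list from 2.12 to 5.80, while podocyte and tubule lists are highest at E18.5.

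At E12.5 the highest ratios included those of the immediate early genes Fosb (42.6 TPM in CPF against 1.05 TPM in DMSO) and Fos (121 against 5.54 TPM), the liver genes Alb (60.9 against 3.89 TPM) and Afp (76.5 against 6.64 TPM), and Mir485. The lowest were Mir196a-2 and Mir196b, which lie within Hox clusters, Mir3470a, Mir6352, Igdcc3 (3.35 against 20.2 TPM) and Hoxd12 (12.1 against 41.4 TPM). Immediate early, erythroid and skeletal muscle lists were at percentile 100, and endothelium and replication-dependent histones at percentile 0.

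At E14.5 the highest ratios were those of germ cell and gonad genes. Dppa3 read 115 TPM in CPF and was listed at 0 in DMSO. Mael read 59.3 against 0.128 TPM and Tex12 51.7 TPM against a listed 0. Cst9 read 102 against 0.576 TPM, Defb19 62.3 against 0.251 TPM, and Cyp17a1, an enzyme of androgen synthesis, 99.6 against 0.537 TPM. The gonad and adrenal cortex lists lay 2.40 and 3.02 above all genes, both at percentile 100. The lowest were the small RNA genes Mir3079, Mir300, Snord68, Scarna17 and Mir483, and Rps2 (133 against 755 TPM), a ribosomal protein gene with many near-identical copies.

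At E16.5 the highest ratios were those of the exocrine pancreas and liver. The pancreatic enzymes Pnliprp1, Ctrb1 and Cpa1 read 917, 913 and 548 TPM in CPF against 1.26, 2.06 and 2.23 TPM in DMSO. The liver genes Alb, Serpina6 and Apoa2 read 2036, 656 and 351 TPM against 5.77, 1.39 and 0.390 TPM. The adrenal cortex list lay 5.25 above all genes and the sympathoadrenal list 2.58. All 6 lowest ratios belonged to small RNA genes (Mir6386, Mir1931, Snord19, Mir196a-1, Mir6412 and Snord37).

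At E18.5 tubule and glomerular genes read higher in CPF. The phosphate transporter of the proximal tubule Slc34a1 read 551 against 83.9 TPM, the water channel of the collecting duct Aqp2 149 against 42.2 TPM, and the slit diaphragm gene Nphs1 25.9 against 3.58 TPM. The proximal tubule list lay 1.96 above all genes, and loop and distal tubule, podocyte, collecting duct and early nephron lists lay 1.49, 1.28, 1.13 and 0.97 above, at percentiles 99.99 to 100. Six2 was among the 6 lowest (8.38 against 35.1 TPM), with Ahcy (4.00 against 21.1 TPM), Mir18, Defb25 and Hbb-y. The highest ratios were those of the liver genes Alb (373 against 2.03 TPM), Trf, Apoa1, Fgg and Serpina6, and the histone gene Hist1h2ba (150 against 2.25 TPM). Erythroid genes, 1.96 to 2.32 above all genes at the earlier stages, lay at -0.73 here.

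The CPF libraries were placed on the time course of the DMSO libraries with 396 genes that changed at least 4-fold between DMSO E12.5 and E18.5. The E12.5 library fell at day 13.4 (95% interval 13.3 to 13.6 over resampled genes, which are not replicates), the E14.5 library at 14.7 (14.6 to 14.8), the E16.5 library at 15.95 (15.8 to 16.2) and the E18.5 library at the last day of the course, E18.5 (lower end of the interval 18.4). Placed the other way, on the CPF course with 826 genes, the DMSO E12.5 library fell at the first day, the E14.5 library at 13.55 (13.45 to 13.7), the E16.5 library at 16.9 (15.9 to 17.0) and the E18.5 library at 17.35 (17.3 to 17.45).

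Between E12.5 and E18.5, 639 genes rose and 510 fell over both agents. Among the largest rises were those of genes of the proximal tubule and its absorptive cells: the calcium-binding S100g (7.93 ± 0.80 on the log2 scale, SE, n = 2 libraries per stage), the brush border protease Mep1a (7.83 ± 0.59), Slc34a1 (7.73 ± 0.63), the sulfotransferase Sult1d1 (7.73 ± 0.41), Spink1 (7.60 ± 0.41), Spp2 (7.34 ± 0.51), the gluconeogenic Fbp1 (7.29 ± 0.68), Keg1 (7.16 ± 0.58) and Hao2 (7.15 ± 0.53). The largest falls were in the embryonic globins Hbb-y (-10.68 ± 1.03) and Hbb-bh1 (-7.95 ± 0.56). Next were the muscle genes Actc1 (-5.13 ± 0.36), Myh3 (-4.93 ± 0.41), Tnnc1 (-4.74 ± 0.41), Myl4 (-4.12 ± 0.39) and Mylpf (-3.88 ± 0.39), the chromatin protein Hmga2 (-3.80 ± 0.29), the chemokine Cxcl13 (-3.31 ± 0.46) and the small RNA AF357355 (-3.14 ± 0.38). Adjusted p from limma for the genes named here ran from 9.77e-07 to 0.00482. All 1149 called genes had the same sign in the CPF libraries alone and in the DMSO libraries alone. Without the filter on low values 394 genes passed. Scaling to coding transcripts moved the median of all genes from -0.21 to -0.0071 and the share of rising calls from 55.6 to 70.9% (1020 and 418 genes).

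All 21 measured proximal tubule genes rose, with a median of 6.01 relative to all genes and Kap (6.71 ± 0.49) and Hnf4a (5.76 ± 0.47) among those with the smallest p. In the collecting duct list 10 of 11 rose, with Aqp2 at 6.23 ± 0.51 and Aqp3 at 4.19 ± 0.43. In the loop and distal tubule list 9 of 12 rose, with Tmem52b at 5.34 ± 0.49 and Sostdc1 at 4.89 ± 0.49. Podocyte genes rose in 5 of 15 (Clic5 4.66 ± 0.48), xenobiotic metabolism genes in 7 of 14 (Fmo1 5.00 ± 0.47, Cyp2j5 6.61 ± 0.71), interferon response genes in 5 of 10 (Ifi44 3.19 ± 0.47) and renal endocrine genes in 3 of 9 (Kl 5.93 ± 0.64, Agtr1a 3.36 ± 0.46). Nephron progenitor genes fell in 4 of 16, among them Osr1 (-2.01 ± 0.38) and Six2 (-1.76 ± 0.36), while Dapl1 rose (1.90 ± 0.49). In the stroma list Foxd1 (-2.52 ± 0.32), Tbx18 (-3.36 ± 0.45) and Aldh1a2 (-1.02 ± 0.28) fell and Penk (3.81 ± 0.49) rose. Skeletal muscle genes fell in 8 of 9 (Myog -5.13 ± 0.45), cell cycle genes in 6 of 19 (Mcm3 -1.24 ± 0.30), Hox genes in 6 of 35 (Hoxd12 -2.23 ± 0.40) and immediate early genes in 3 of 14 (Ier2 -1.53 ± 0.33). In limma's camera 23 of 40 lists passed, led by proximal tubule (adjusted p = 1.09e-37), collecting duct (1.26e-14), and loop and distal tubule (8.43e-13). None of the 40 passed with an estimated correlation, where the adjusted p of these 3 lists was 0.487, 0.487 and 0.512.

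No gene passed the test of a CPF effect on the change with embryonic day (limma, smallest adjusted p 0.132, 3615 genes at an unadjusted p under 0.05). Of these 3402 had a higher slope in CPF. With quantile normalization 0 passed in limma and 1374 had an unadjusted p under 0.05. That number was 1612 with scaling to coding transcripts, 1915 without the E12.5 pair and 906 without the E18.5 pair, again with 0 passing in limma. The genes with the smallest p and a higher slope in CPF were the sterol enzyme Nsdhl (0.37 ± 0.05 log2 units per day, SE), Syngr2 (0.35 ± 0.06), Mir6898 (0.73 ± 0.12), Acsl1 (0.38 ± 0.07) and the folate enzyme Mthfd1 (0.31 ± 0.05). Those with a lower slope were Crabp2, which binds retinoic acid (-0.28 ± 0.05), Snora65 (-0.32 ± 0.06), Wfdc17 (-0.48 ± 0.10), Snora70 (-0.49 ± 0.11) and Mir7685 (-0.61 ± 0.14), and none of these 10 passed. Of 40 lists, 15 passed camera. Endothelium, Notch pathway and cholesterol biosynthesis had higher slopes in CPF, by 0.28, 0.19 and 0.12 log2 units per day relative to all genes, and erythroid (-0.45) and skeletal muscle (-0.37) genes were among the 12 with lower slopes. None passed with an estimated correlation, where the adjusted p was 0.902 for each of these 5 lists.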

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

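The tests of liver, gonad and pancreas markers, of the developmental position and of transcript length were fixed before their results were seen, and so were the counts over other splits; the tests of scaling, of dilution and of a later stage at E18.5 alone were chosen after the result was seen, and so was leaving E18.5 out of the test of a later stage and counting each contrast once. The limits for a difference between stages (percentiles 1 and 99 of random lists, most extreme pair) were tightened after a wider limit had listed too many. Dixon's rule for 4 values set apart 6 of 69 groups of 4, against about 1 in 20 by chance. In the CPF minus DMSO difference these were Acta2 at E16.5 (2.13), Nphs1 at E18.5 (2.55), and, relative to all genes, the ureteric bud (0.27), podocyte (1.28) and erythroid (-0.73) lists at E18.5 and the Hox list at E16.5 (-0.87).

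Several lists lay at opposite ends of the matched random lists at different stages, a difference that was not tested because each stage has 1 library per agent. Relative to all genes, podocyte genes lay at -0.41 at E16.5 and 1.28 at E18.5, endothelium at -0.62 at E12.5 and 0.91 at E18.5, erythroid genes at 2.03 at E12.5 and -0.73 at E18.5, ribosomal protein genes at 0.27 at E12.5 and -0.64 at E18.5, and replication-dependent histones at -0.45 at E12.5 and 0.42 at E16.5. In the test of slopes over embryonic day, the lists that passed camera differed by these log2 units per day relative to all genes: endothelium 0.28, Notch pathway 0.19, cholesterol biosynthesis 0.12, erythroid -0.45, skeletal muscle -0.37, cartilage -0.22, immediate early -0.22, adrenal cortex -0.22, Y-linked -0.19, sympathoadrenal -0.15, ribosomal proteins -0.15, stroma -0.10, inflammation -0.10, nephron progenitor -0.085 and histones -0.037. None passed with an estimated correlation, and 25 of the 35 splits of the 8 libraries gave at least as many lists as the real 15, up to 24, so chance was not excluded for them.

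Transcripts of other organs were higher in CPF libraries. Of further markers that were detected, 88.0% of 25 pancreas genes, acinar and islet alike, were highest in CPF at E16.5 (Clps 273 TPM, Gcg 55.3 TPM, Ins1 19.4 TPM), 82.4% of 17 gonad genes were highest in CPF at E14.5 (343 TPM summed, against 38.1 TPM in DMSO), and 92.9% of 14 liver genes were higher in CPF at all 4 stages. The tables argue against scaling by short non-coding RNA, since the median of the liver list itself went from 3.59 to 3.43 once libraries were scaled to coding transcripts, which moved the median of all genes from 0.15 to -0.0073. A candidate explanation is RNA of adjacent liver, pancreas, adrenal and gonad left on the dissected kidneys; the DMSO library of E14.5 also held 278 TPM of Alb. Summed from E12.5 to E18.5, the pancreas genes read 17.3, 16.8, 637 and 51.2 TPM in CPF, and at most 18.7 TPM in DMSO. The gonad genes read 39.8, 343, 83.5 and 19.97 TPM in CPF, and at most 38.1 TPM in DMSO. For pancreas and gonad genes this argues against a CPF effect of similar size at all 4 stages. Liver genes, mostly higher in CPF at every stage, are not covered. Any other effect of CPF on these transcripts within the kidney, including one at a single stage, was not tested. It stays open, since each agent and stage has 1 library.

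Nephron progenitor genes were lower in CPF. The tables argue against scaling as the cause, since the median of the list itself went from -0.67 to -0.89 after scaling to coding transcripts. They also argue against a later stage of the CPF kidneys as the whole cause at E12.5, E14.5 and E16.5. These CPF libraries were placed at day 13.4, 14.7 and 15.95 of the DMSO course, so the E16.5 library was not placed later than its stage. At the placed days the list still lay at -0.43, -0.79 and -0.87 relative to all genes (median -0.79). The placements were loose, with root mean square distances of 0.78, 0.94 and 1.18 log2 units from the course. At E18.5 the DMSO library lay 0.96 ± 0.19 (SE over the genes of the list) above the CPF course at the day where it was placed, 17.35. That part of the course joins the CPF libraries of E16.5 and E18.5, both already low in the list at their own stages (-0.79 and -0.95). The comparison therefore cannot decide about a later stage at E18.5. Dilution by RNA of other organs would lower kidney lists alike only if those organs lacked their genes, which was not tested. The progenitor list lay below the 103 genes of the 7 other kidney lists by -0.59 ± 0.12, -0.71 ± 0.17, -0.57 ± 0.17 and -1.92 ± 0.24 from E12.5 to E18.5 (SE over genes, mean -0.95, or -0.62 without E18.5). Against the 44 genes of the ureteric bud, early nephron and stroma lists together the gap was -0.42 ± 0.15, -0.68 ± 0.18, -0.69 ± 0.19 and -1.15 ± 0.25. Against single lists the gap was smallest relative to its SE for ureteric bud at E12.5 (-0.23 ± 0.14), podocyte at E12.5 and E16.5 (-0.31 ± 0.21 and -0.38 ± 0.23) and stroma at E16.5 (-0.47 ± 0.26). These values do not decide whether dilution was the whole cause, because the share of these genes in the other organs was not tested. An effect of CPF on the progenitors and dilution, as a part or the whole of the difference, stay open. So do a later stage at E18.5, a later stage as a part of the difference at E12.5, and a difference in which part of the kidney was taken.

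At E18.5 many more transcripts were higher than lower in CPF. The shift of all genes follows the share of Rpph1 and Rmrp in the DMSO library, as the median log2 ratio went from 0.53 to 0.14 once libraries were scaled to coding transcripts. The same scaling took the median of the proximal tubule list itself from 2.50 to 2.03, which argues against it as the whole cause of the tubule difference. RNA breakage or length selection cannot be told apart from other causes, because the log2 ratio followed transcript length weakly (Spearman rho 0.218 across 10810 genes, against -0.124, 0.0605 and -0.0208 at the earlier stages). An effect of CPF and a later developmental stage stay open: the DMSO library fell at day 17.35 of the CPF course, while the CPF library fell at the end of the DMSO course, or at day 17.75 with a log2 limit of 1.

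Splits of the 8 libraries, the real one among them, were counted. With stage in the fit they give 20 distinct contrasts. Of these 2, the real one and 1 other with 59, gave at least the 22 genes of the real split, so chance was not excluded. The contrast with 59 sets the CPF libraries of E14.5 and E16.5 against the DMSO libraries of these stages, so it holds part of the real contrast and points to a structure in those 4 libraries. Of the 8 splits that part the libraries of all 4 stages the real split gave 22 genes and the highest other 0, which are too few splits for a share under 0.05. For gene lists, 3 of the 20, the real one among them, gave at least 22 lists, up to 23, so chance was not excluded. For the slopes, the real split gave 3615 genes at an unadjusted p under 0.05 and 1 of the 35 splits, the real one, reached that count, with 3267 in the highest other. Of the 8 splits that part all 4 stages the highest other gave 2845, and these are too few splits for a share under 0.05. The real count was 1374 with quantile normalization, 1612 with coding scaling, 1915 without the E12.5 pair and 906 without the E18.5 pair.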

How the results depend on the processing

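Scaling to coding transcripts, genes with 1 RefSeq transcript, leaving out E14.5 with E16.5, and quantile normalization of the lists were chosen after seeing the data, and so was leaving Ret and Cited1 out of the fold changes compared here (the sign of Ret had turned under several alternatives). The cause was not tested unless stated. For CPF against DMSO (22 genes) limma gave 0 with quantile normalization (1485 at an unadjusted p under 0.05), 0 without a filter (1537), 0 with no replicate block (656), 0 with day as a linear covariate (1262), 92 with the stricter filter, 83 with pseudocount 0.1, 1 with scaling to coding transcripts, 34 without E14.5 and E16.5 (1 residual degree of freedom) and 25 (without E16.5) to 221 (without E14.5) when 1 stage pair was left out. Of the 22 genes, 21 passed without E12.5, 22 without E14.5, 7 without E16.5, 13 without E18.5 and 2 without E14.5 and E16.5. For E18.5 against E12.5 (1149) it gave 394 without a filter, where more genes are tested, and 1077 to 1711 elsewhere. The slope count was 0 in every setting run. Over the alternatives, 213 values of named genes in CPF minus DMSO and 234 in E18.5 minus E12.5 kept direction and side of the threshold, 73 and 3 lost the call, and 6 and 0 gained it. With 1 stage pair left out Wnt4 ranged from -0.10 to 0.73, Nphs1 from -0.095 to 0.84 and Aqp2 from -6.7e-06 to 0.69, each lowest without E18.5.

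The lists passing camera went from 22 to 0 with an estimated correlation and 1 with fry, and were 21 to 27 in the other settings. With an estimated correlation they went from 23 to 0 for E18.5 against E12.5 and from 15 to 0 for slopes. Of list values in CPF minus DMSO, 240 kept direction and side, 24 gained and 34 lost the call, and 22 turned direction in camera, none of them of a called list. With 1 stage pair left out, their medians relative to all genes ranged from -0.088 to 0.31 (endothelium, turned without E12.5, 0.24, and without E14.5), -0.22 to 0.17 (p53 targets, turned without E18.5 and without E12.5, -0.035), -0.15 to 0.050 (Wnt targets), -0.090 to 0.26 (Notch, turned without E18.5 and without E16.5, 0.047), -0.082 to 0.23 (cartilage), and, turned without E18.5, -0.023 to 0.27 (early nephron), -0.15 to 0.45 (loop and distal tubule), -0.14 to 0.41 (podocyte), -0.18 to 0.068 (cell cycle) and -0.28 to 0.13 (ribosomal proteins). Camera's direction also turned for endothelium (0.13), cartilage (0.027) and Wnt targets (0.023) with coding scaling, for endothelium (0.11), cartilage (0.014) and p53 targets (-0.059) with quantile normalization, and for endothelium (0.20), ER stress (-0.061) and Y-linked genes (-0.090) without E14.5 and E16.5.

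Genes over 2-fold at the 4 stages (508, 522, 695 and 2345) numbered 249, 186, 264 and 1354 at a minimum mean of 20 TPM, where fewer genes enter. At E18.5 they numbered 1082 with quantile normalization and 1257 with coding scaling. With a log2 limit of 1 the placement was day 13.8, 14.9 and 17.8 for E12.5, E14.5 and E18.5, and it stayed within the interval in the other settings. Count-based alternatives were not run because the values are TPM. Since 1 read in 1 kb was worth up to 0.105 TPM, values near that are not resolved. In shorter transcripts, such as those of small RNA genes, 1 read is worth more, so larger values are not resolved either.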

Other observations

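Embryonic globin was abundant in the early CPF libraries. Hbb-y read 33813, 15633, 521 and 4.07 TPM in CPF from E12.5 to E18.5 and 6940, 3738, 461 and 16.2 TPM in DMSO, and embryonic globins took 3.66% of the TPM at E12.5 in CPF and 0.803% in DMSO. Adult globins, which have near-identical copies, were not read.

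Transcripts of both sexes were present in all 8 libraries. Xist, which silences an X chromosome in females, read 91.4, 118, 41.4 and 89.6 TPM in CPF and 78.7, 142, 109 and 34.6 TPM in DMSO, and the Y-linked Ddx3y read 58.9, 64.4, 70.2 and 58.9 TPM in CPF and 46.1, 29.7, 46.3 and 61.1 TPM in DMSO. Of 9 lung markers 2 were detected, and these, Sftpc and Lamp3, were at or below 1.64 and 1.49 TPM in each library.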
